A study of Bos taurus with 16 samples.

How the data were processed

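Corpora lutea, the transient endocrine glands that form on the ovary after ovulation, came from 16 cattle found to be pregnant, 4 each at day 14, day 17, day 20 and day 23 from breeding. Per the labels' protocols, total RNA that included miRNA was extracted with a commercial kit and its quality was measured. MicroRNAs were counted on the NanoString platform, in which colour-coded probes are hybridised to RNA molecules and counted without amplification. Per the labels, the samples were processed in 2 NanoString runs. Each run held 8 samples, 2 from every day, so day and run could be fitted together. RNA sequencing is also mentioned in the series' design text and was not analysed here.

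One deposited table held 204 miRNA probes in 16 sample columns. The values are a non-negative signal that the authors called normalized counts. The counting software, the probe panel, the background correction, the normalization and any filter are not given in the sources used here. The probes carry human miRNA names, and 9 of them name several miRNAs that the probe cannot tell apart. Probes for members of one family, such as let-7, differ by few bases, and shared signal between them was not measured. The values ran from 12.0 to 132328, none was 0, and no control probes were among the 204. Low values in each column lay on evenly spaced steps, with 1 step worth 0.665 to 2.91 normalized counts and a shift that was not 0. Original counts were therefore not recovered, no count model was used, and no counting interval is given. Column totals ran from 175197 to 536516. All 16 columns were matched to samples by their names.

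Names were compared with the RefSeq gene table of the ARS-UCD2.0 cattle assembly, which lists 1032 miRNA genes. Of the 204 probes, 156 had a bovine gene of the same name, 10 had one of the same number with another letter, and 38 had neither. The table was used for names and for which genes neighbour each other, and no coordinates are given because the source of the probe panel is not stated.

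Values were transformed as log2(normalized count + 1) with no further scaling, and log2 differences are on that scale, which understates changes of low probes. Probes with a normalized count of at least 20 in at least 4 samples were to be tested; all 204 passed. One linear model per probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) to all 16 samples, with day as a factor and run as a covariate, which left 11 residual degrees of freedom. Tests covered the 4 days together, the 6 pairs of days, a linear slope on day, and run 2 against run 1. P-values were adjusted by the Benjamini-Hochberg method within each test, and an adjusted p under 0.05 was called. Every unadjusted count given here is at p under 0.05, where chance gives 10.2 of 204 probes.

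The tests, the thresholds, the lists, the alternatives and the rule for named miRNAs were written before the data were examined. By that rule, named miRNAs were up to 10 called in each direction per comparison. Where fewer than 5 were called, the 5 with the smallest p were added, with values only. Called list members, 2 to 4 of the most abundant members of each list described, and the 10 most abundant miRNAs were also named. Of 19 lists of miRNA families, genomic clusters and cell type markers, 14 had at least 3 measured members. These were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, both two-sided and adjusted over the lists within each comparison. For the lists that were called, a score per sample was the mean log2 value of the members minus that of all probes. Scores were compared between days by exact two-sided permutation over all 70 arrangements of 8 samples, after centring within each run. Exact here means that all 70 were counted. They include arrangements that move samples between runs. Shuffling within runs, which was not done, allows fewer arrangements and only a larger smallest p. Sample totals were compared in the same way, the centring of totals having been added after the data were seen.

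The fit was tested on simulated data for day 23 against day 14, with 20 sets of 204 probes and 40 probes changed per set. It recovered 67% of changes of 1 log2 unit and 98.3% of changes of 2 log2 units, and 5.84% of calls were false. With no probe changed, 2 of the 20 sets gave a call, and sets averaged 0.35 list calls over the pairs of days. Noise was drawn independently for each probe, so these rates do not cover correlation between probes. Samples of the same day and run differed by 0.475 to 0.871 log2 units (root mean square over probes), so none of these pairs were duplicates. Pairs across days or runs were not compared in this way. Samples with the same replicate number deviated together from their day means in all 24 pairs (Pearson r across probes of 0.19 to 0.81). This followed from the run, because replicates 1 and 2 were always run 1 and replicates 3 and 4 always run 2. Once day and run were both removed, r ran from -0.60 to 0.57 and only 9 of 24 pairs exceeded 0.1. The median r was -0.077, against -0.26 for samples of the same run with another number. The numbers therefore paired samples mainly through the run, which the main model holds. A weaker pairing by number is not excluded, and a replicate block was kept as an alternative.

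Alternatives were other pseudocounts (0.5 and 10), a filter at 100, no filter, no run term, a replicate block, rescaling to one geometric mean, quantile normalization, a variance without trend, each run alone, each pair of days alone, and each sample left out in turn. Chosen after seeing the data were a fit of only the probes with a bovine gene, a fit without the samples of lowest and highest total, the DLK1-DIO3 list without miR-342-3p, and the estimated correlation for single lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.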

Results

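MicroRNA levels were measured in the corpus luteum of pregnant cattle at 4 times in early pregnancy, to follow how the gland's miRNAs change from day 14 to day 23 after breeding. The corpus luteum makes the progesterone that maintains pregnancy, and in cattle these days span the time when the embryo signals its presence to the mother. Each day had 4 samples, 2 in each of 2 NanoString runs. Totals were 329108 ± 163976 normalized counts on day 14 (SD, n = 4), 339872 ± 93250 on day 17, 363116 ± 98794 on day 20 and 382168 ± 120566 on day 23. Centred within runs, no pair of days differed in total by exact permutation. The smallest two-sided p was 0.229, for day 23 against day 14, where 70 arrangements can reach 0.0286; that difference was 98086 in run 1 and 8034 in run 2.

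The luteal profile was led by the let-7 family, miRNAs abundant in differentiated tissues. let-7a-5p averaged 75573 ± 27473 normalized counts (SD, n = 16) and let-7b-5p 59749 ± 22482. Between them they made up 31.6% to 46.0% of each sample's total. The other high counts, by means over both runs, were those of miR-125b-5p at 19094 ± 6599 and miR-126-3p, an endothelial miRNA, at 14686 ± 8100. The probe shared by miR-4454 and miR-7975, which has no bovine gene of those names or numbers, averaged 14291 ± 8152. Next were let-7c-5p at 12382 ± 3459, let-7d-5p at 10529 ± 5079, miR-181a-5p at 9458 ± 5499, the probe shared by miR-199a-3p and miR-199b-3p at 6901 ± 3123, and let-7i-5p at 6287 ± 2382. The order differed by run: in run 1 miR-126-3p averaged 9172, below let-7c-5p at 9825, and in run 2 it averaged 20199 and let-7c-5p 14938.

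Across the 4 days, no single miRNA passed the adjusted threshold. miR-432-5p, a miRNA of the imprinted DLK1-DIO3 region, had the smallest adjusted p (0.164 by limma), and 17 of 204 probes had an unadjusted p under 0.05. As a linear slope over days, miR-432-5p fell by 0.133 log2 units per day (SE 0.030, adjusted p = 0.0388) and was the only call among 48 probes under an unadjusted p of 0.05, of which 30 sloped up and 18 down. The next 4 slopes were upward and not called. miR-181a-5p had 0.131 per day (SE 0.034, adjusted p = 0.0731), miR-30d-5p 0.111 (SE 0.030, adjusted p = 0.0738), miR-331-3p 0.124 (SE 0.036, adjusted p = 0.0830) and the probe shared by miR-365a-3p and miR-365b-3p 0.120 (SE 0.035, adjusted p = 0.0830). The slope of miR-432-5p was not called without the run term (adjusted p = 0.530), nor in either run alone (-0.107 per day, adjusted p = 0.0838 in run 1; -0.160, adjusted p = 0.231 in run 2), and 9 of the 16 fits that left out a sample lost it.

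Day 23 against day 14 spans the whole interval and held the clearest difference. miR-432-5p fell 2.5-fold, a log2 difference of -1.32 (SE 0.28, adjusted p = 0.0204). It averaged 204 ± 76.4 normalized counts on day 14 (SD, n = 4), 151 ± 38.0 on day 17, 149 ± 35.6 on day 20 and 79.9 ± 27.7 on day 23. All 4 day 23 samples (54.0 to 119) lay below all 4 day 14 samples (126 to 291). The mean went from 141 to 65.4 in run 1 and from 267 to 94.4 in run 2, with 2 samples per day in each run. In run 1 both means lay below the sample medians of probes without a bovine gene, which averaged 160. In run 2 both lay above those medians, which averaged 57.5. How much of the miR-432-5p signal was background was not tested.

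**Figure D1:**
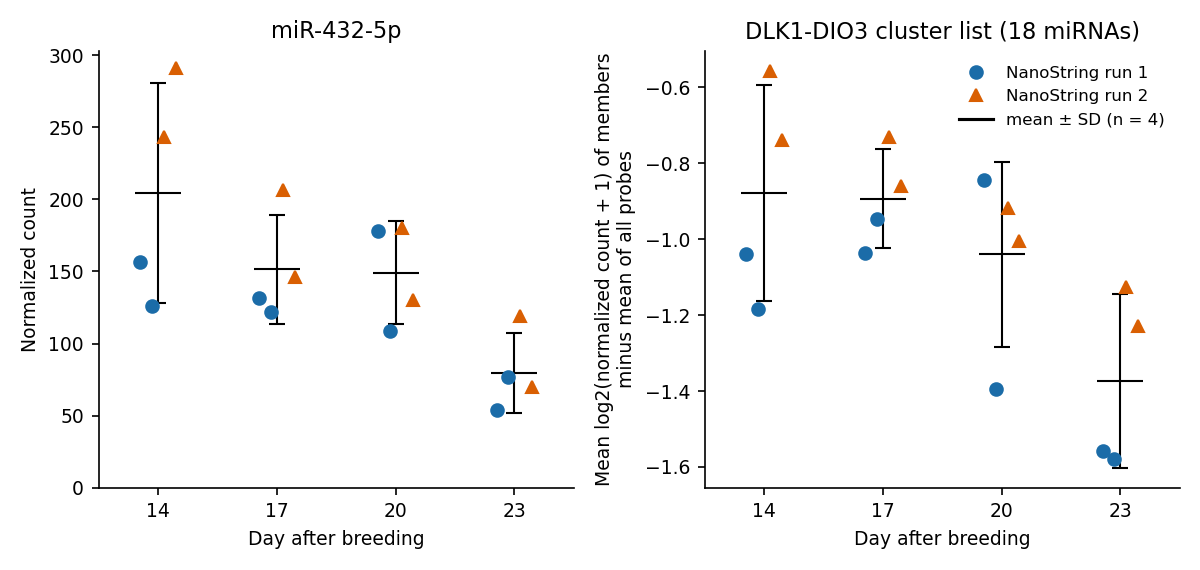
Left, normalized count of miR-432-5p in each of 16 samples by day after breeding; right, the DLK1-DIO3 list score (mean log2 of the 18 members minus the mean of all probes). Points are samples, shaped and coloured by NanoString run, and bars are the mean ± SD of 4 samples; miR-432-5p averaged 204 on day 14 and 79.9 on day 23, and in each run both day 23 scores lie below the scores of the 6 samples of other days.

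The next 4 miRNAs had the smallest p-values of this comparison without passing the threshold. miR-181a-5p averaged 6214 ± 3232 on day 14 and 14854 ± 7702 on day 23, a log2 difference of 1.26 (SE 0.33, adjusted p = 0.0810). The probe shared by miR-365a-3p and miR-365b-3p differed by 1.20 (SE 0.33, adjusted p = 0.0810) and miR-27b-3p, which is processed from the same transcript as miR-23b, by 0.82 (SE 0.24, adjusted p = 0.0993). The probe shared by miR-548z and miR-548h-3p, which has no bovine gene of that number, differed by -1.05 (SE 0.29, adjusted p = 0.0810). In run 1 and run 2 alone these values were 1.52 and 1.01 for miR-181a-5p, 1.23 and 1.17 for the miR-365 probe, 1.16 and 0.48 for miR-27b-3p, and -1.18 and -0.91 for the miR-548z probe; all 4 were called with run 1 alone and none with run 2 alone. In all, 43 probes had an unadjusted p under 0.05, 27 of them higher and 16 lower on day 23. The call of miR-432-5p was lost without the run term (adjusted p = 0.609), in a fit of these 8 samples alone (0.0842), with run 2 alone (-1.54, adjusted p = 0.405; run 1 alone -1.11, adjusted p = 0.0171), and on leaving out day 14 replicate 1 (0.0554), day 14 replicate 3 (0.0795), day 23 replicate 1 (0.132) or day 23 replicate 4 (0.147). Without day 14 replicate 4 there were 3 calls and without day 23 replicate 3 there were 10, against 1 with all samples. With run 1 alone there were 40 calls, 25 higher and 15 lower, of which 20 had the same direction in run 2, and 10 of the 15 lower had no bovine gene. Of all samples, day 14 replicate 1, of run 1, had the highest median of probes without a bovine gene (258 normalized counts). It also had the lowest median of probes with one (163) and the lowest total. With run 2 alone there were 0 calls by limma, with 19 under an unadjusted p of 0.05, and the Pearson r between runs over all probes was -0.0248. A test of whether the day 23 effect differed between runs called 0 probes, with 39 under an unadjusted p of 0.05.

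The DLK1-DIO3 imprinted cluster, a large group of miRNA genes expressed from the maternal chromosome, was lower as a list on day 23. Of 18 measured members, 16 had lower values than on day 14, with a median log2 difference of -0.56 (camera adjusted p = 5.2e-05). The adjusted p was 0.225 with an estimated correlation, so the call rested on the preset one. Within runs the median was -0.26 in run 1 and -0.76 in run 2 (adjusted p = 0.0380 and 0.0047 by limma). miR-432-5p was the 1 member called over all probes and the 1 called when adjusted over the list alone. The most abundant members were not called singly. They were miR-127-3p with -0.75 (SE 0.29, adjusted p = 0.143), miR-379-5p with -0.57 (SE 0.32, adjusted p = 0.310), miR-382-5p with -0.48 (SE 0.30, adjusted p = 0.387) and miR-409-3p with -0.57 (SE 0.26, adjusted p = 0.204). In the cattle assembly ARS-UCD2.0, 17 of the 18 members lie in one stretch of 58 neighbouring miRNA genes. miR-342-3p, which lies outside it on the same chromosome, was 1 of the 2 members with a higher value (0.47, SE 0.31, adjusted p = 0.413).

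**Figure D2:**
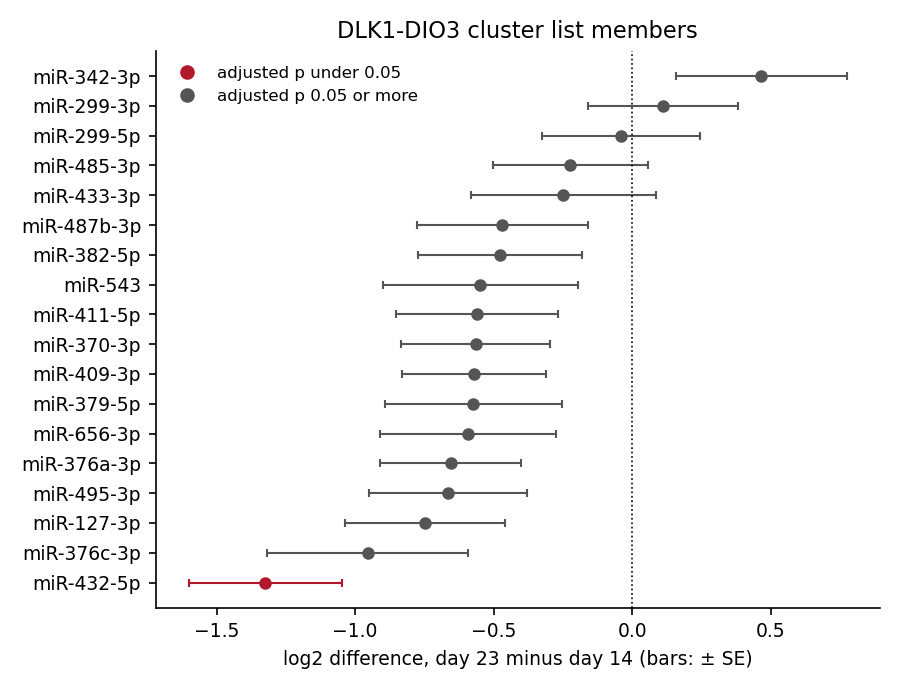
Log2 difference (day 23 minus day 14, horizontal axis) of the 18 measured miRNAs of the DLK1-DIO3 list, 1 per line, with bars of ± 1 SE from the limma fit. Of the 18, 16 lie below 0, and miR-432-5p, at -1.32, is the 1 member with an adjusted p under 0.05.

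The list score of the cluster averaged -0.88 ± 0.28 on day 14 (SD, n = 4) and -1.37 ± 0.23 on day 23, a difference of -0.49. The exact permutation p was 0.0286, the smallest that 70 arrangements allow, and 0.114 after adjustment over 12 score tests. These arrangements cross the runs, and shuffling within runs could not give so small a p. The 12 tests covered only lists already called in these data, which the adjustment does not take into account. The difference was -0.46 in run 1 and -0.53 in run 2. In run 1 the day 23 scores were -1.58 and -1.56, below the -1.39 to -0.84 of the other 6 samples, and in run 2 they were -1.23 and -1.13, below the -1.0 to -0.56 of the other 6.

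None of the other 13 lists tested was called for day 23 against day 14. The 3 probes of the miR-181 family were all higher, with a median of 0.97 (adjusted p = 0.0840), and miR-181a-5p and miR-181c-5p passed when adjusted over the list alone. The let-7 family (9 probes) had a median of 0.34 (adjusted p = 0.126), with let-7a-5p at 0.44 and let-7b-5p at 0.56. The miR-30 family (7 probes) had 0.25 (adjusted p = 0.204), and miR-30d-5p passed when adjusted over the list alone. Leukocyte miRNAs (7 probes) had -0.56 (adjusted p = 0.198), with miR-21-5p at -0.56, miR-150-5p at -0.18 (but 0.94 in run 1 alone) and miR-155-5p at -0.75. The X-linked cluster of miR-424 and miR-450 (6 probes) had -0.44 and the miR-99/100 and miR-125 family (5 probes) 0.26, both with adjusted p = 0.443. Endothelial and angiogenic miRNAs (10 probes) had 0.24 (adjusted p = 0.663), among them miR-126-3p at -0.46 and miR-27b-3p, which passed when adjusted over the list alone. The miR-17 to miR-92 clusters (9 probes) had -0.15 (adjusted p = 0.443). The remaining 5 lists had adjusted p = 0.893. Their medians were 0.25 for the miR-29 family, -0.33 for the miR-15/16 family, -0.01 for steroidogenic and gonadotropin-responsive miRNAs, -0.04 for smooth muscle, pericyte and fibroblast miRNAs, and 0.06 for the primate-specific chromosome 19 cluster.

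Against day 17, day 23 showed no called miRNA, with 24 probes under an unadjusted p of 0.05 by limma, 14 higher and 10 lower. The DLK1-DIO3 list was again lower, in 17 of 18 members, with a median of -0.44 (camera adjusted p = 9.7e-07; adjusted p = 0.0920 with an estimated correlation), and of -0.67 in run 1 and -0.36 in run 2. The probes with the smallest p were miR-432-5p at -0.94 (SE 0.28), miR-328-3p at 1.08 (SE 0.36), miR-143-3p at -1.07 (SE 0.37), miR-574-5p at 1.02 (SE 0.35) and miR-376c-3p at -1.03 (SE 0.36), each with adjusted p = 0.363. With each sample left out in turn, miR-143-3p ran from -1.33 to -0.75 and miR-376c-3p from -1.40 to -0.74. Both were nearest 0 without day 17 replicate 4, where their counts were far above those of the other day 17 samples. Adjusted over the list alone, miR-432-5p passed in its cluster, and miR-143-3p, a smooth muscle miRNA, passed in the smooth muscle, pericyte and fibroblast list. That list had 5 of 6 members lower, with a median of -0.30 (adjusted p = 0.120), and the miR-181 family had 0.75 (adjusted p = 0.153). The DLK1-DIO3 score differed by -0.48 (exact permutation p = 0.0286, adjusted 0.114), with -0.58 in run 1 and -0.38 in run 2.

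Against day 20, day 23 again had no called miRNA, and 10 probes were under an unadjusted p of 0.05 by limma, 5 in each direction. The DLK1-DIO3 list was lower in 14 of 18 members, with a median of -0.41 (camera adjusted p = 1.0e-04; adjusted p = 0.266 with an estimated correlation), and 0 members passed when adjusted over the list alone, against 4 at an unadjusted p under 0.05. miR-432-5p had -0.92 (SE 0.28, adjusted p = 0.656). The next smallest p-values were those of the probe shared by miR-365a-3p and miR-365b-3p at 0.89 (SE 0.33), miR-197-3p at 0.99 (SE 0.40), miR-574-5p at 0.80 (SE 0.35) and miR-328-3p at 0.79 (SE 0.36), each with adjusted p = 0.811. The next lists were leukocyte miRNAs with a median of -0.53 and smooth muscle, pericyte and fibroblast miRNAs with -0.36, both with adjusted p = 0.0723, and the miR-181 family with 0.68 (adjusted p = 0.0761). The score of the cluster differed by -0.33 (exact permutation p = 0.0286, adjusted 0.114), with -0.45 in run 1 and -0.22 in run 2. The comparisons of day 23 with days 14, 17 and 20 share the 4 day 23 samples and are not independent. With run 2 alone, the list was not called against day 20 (median -0.23, adjusted p = 0.151; run 1 alone -0.47).

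On day 17 against day 14, smooth muscle, pericyte and fibroblast miRNAs were higher as a list. All 6 probes had positive differences, with a median of 0.32 (camera adjusted p = 0.0353; adjusted p = 0.676 with an estimated correlation). The most abundant members were the probe shared by miR-199a-3p and miR-199b-3p with 0.12, miR-145-5p with 0.57 (SE 0.24), miR-199a-5p with 0.40 and miR-214-3p with 0.24, and 0 members passed when adjusted over the list alone, against 1 at an unadjusted p under 0.05. No single miRNA was called by limma, and 5 of 204 were under an unadjusted p of 0.05, fewer than chance gives. These were miR-577 at -0.84 (SE 0.25, adjusted p = 0.565), the probe shared by miR-548z and miR-548h-3p at -0.77 (SE 0.29), miR-145-5p, miR-548ah-5p at -0.59 (SE 0.26) and miR-125b-5p at 0.62 (SE 0.29), the last 4 with adjusted p = 0.963. miR-577 and both miR-548 probes have no bovine gene of their name or number. The list score differed by 0.36 (exact permutation p = 0.229), with 0.64 in run 1 and 0.09 in run 2. The probe shared by miR-199a-3p and miR-199b-3p had 1.06 in run 1 alone. Both runs weigh equally in the fit, so its difference in run 2 was below 0. The list call was lost with run 2 alone (median 0.14, adjusted p = 0.844; run 1 alone 0.76) and without any one of 5 samples, among them day 14 replicate 1 (median 0.15, adjusted p = 0.396).

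On day 20 against day 14 no miRNA and no list was called, and 13 probes had an unadjusted p under 0.05 by limma, 8 higher and 5 lower. miR-125b-5p had the smallest p, with a log2 difference of 0.83 (SE 0.29), from 13694 ± 7788 normalized counts on day 14 (SD, n = 4) to 21735 ± 5007 on day 20. It was followed by let-7c-5p at 0.58 (SE 0.23), miR-145-5p at 0.61 (SE 0.24), miR-542-5p at 0.81 (SE 0.32) and miR-656-3p at -0.79 (SE 0.32), all with adjusted p = 0.679. The nearest lists were the let-7 family with a median of 0.29, higher in 8 of 9 probes, and the miR-99/100 and miR-125 family with 0.32, higher in 5 of 5, both with adjusted p = 0.0806. Apart from miR-542-5p these values were larger in run 1: in run 1 and run 2 alone they were 1.39 and 0.27 for miR-125b-5p, 1.08 and 0.08 for let-7c-5p, 1.14 and 0.08 for miR-145-5p, 0.59 and 1.04 for miR-542-5p, and -1.49 and -0.10 for miR-656-3p. With run 1 alone there were 31 calls, 19 higher and 12 lower, of which 11 had the same direction in run 2, and 10 of the 12 lower had no bovine gene. Day 14 replicate 1, described above, is a run 1 sample, and how far it shaped these calls was not tested. Across probes, the difference rose with mean level (Spearman 0.38, and 0.37 for day 17 against day 14). With run 2 alone there were 0 calls by limma, with 6 under an unadjusted p of 0.05, and the Pearson r between runs over all probes was -0.12. A test of whether the day 20 effect differed between runs called 0 probes, with 32 under an unadjusted p of 0.05.

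On day 20 against day 17 no miRNA and no list was called, and 1 probe, miR-4516, had an unadjusted p under 0.05 by limma. It had a log2 difference of -1.39 (SE 0.62). miR-542-3p had -0.63 (SE 0.31), miR-141-3p, an epithelial miRNA, 0.48 (SE 0.25), the probe shared by miR-4454 and miR-7975 0.88 (SE 0.46), and miR-378h 0.49 (SE 0.26), all 5 with adjusted p = 0.972. miR-4516 and the probe shared by miR-4454 and miR-7975 have no bovine gene of their name or number. The DLK1-DIO3 list had a median of -0.11, lower in 14 of 18, and the X-linked cluster -0.29, lower in 5 of 6, both with adjusted p = 0.0695.

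The 2 NanoString runs differed far more than the days. Of 204 probes, 170 differed between runs by limma, 135 of them higher and 35 lower in run 2. The largest differences upward were those of miR-132-3p, 2.91-fold (log2 1.54, SE 0.30), miR-451a, an erythrocyte miRNA, 2.90-fold (log2 1.54, SE 0.31), miR-424-5p, 2.62-fold (log2 1.39, SE 0.28), and miR-21-5p, 2.60-fold (log2 1.38, SE 0.23), with adjusted p-values from 4.8e-05 to 2.8e-04. miR-222-3p, miR-30d-5p, miR-542-3p, miR-92a-3p, miR-652-3p and miR-27b-3p were 2.30-fold to 2.5-fold higher. Downward, miR-522-3p, a member of the primate-specific chromosome 19 cluster, was 11.7-fold lower in run 2 (log2 -3.55, SE 0.25, adjusted p = 4.0e-10) and miR-1297 was 9.07-fold lower (log2 -3.18, SE 0.28). The probe shared by miR-548z and miR-548h-3p was 7.14-fold lower, miR-548n 6.12-fold, miR-1290 5.90-fold, miR-4455 5.44-fold, miR-944 4.65-fold, miR-644a 4.45-fold, miR-590-5p 4.22-fold and miR-548g-3p 3.68-fold. No list was called between runs (smallest camera adjusted p = 0.203), while 9 of 9 let-7 probes and 16 of 18 DLK1-DIO3 probes differed singly. Of the 5 probes of the chromosome 19 cluster, 3 were lower in run 2 and 2 higher. Among the higher was miR-518b, at 2.26-fold (log2 1.18, SE 0.21).

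**Figure D3:**
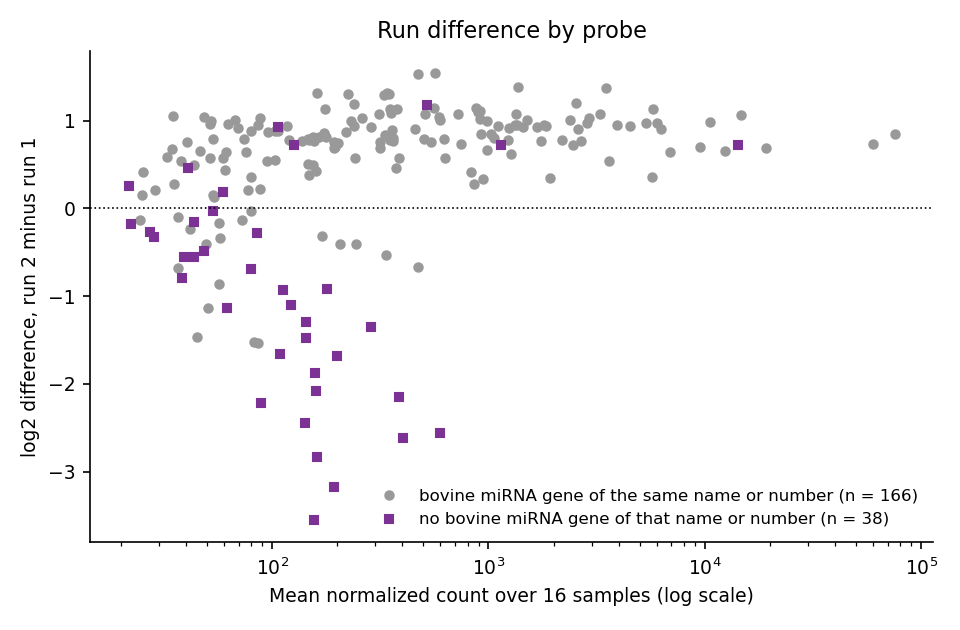
Log2 difference between runs (run 2 minus run 1, vertical axis) of each of 204 probes against its mean normalized count over 16 samples (log scale, horizontal axis). Squares are the 38 probes with no bovine miRNA gene of that name or number, with a median of -0.86, and circles the other 166, with a median of 0.79.

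Sample totals were 259036 ± 48488 in run 1 (SD, n = 8) and 448095 ± 62093 in run 2, 1.73-fold higher (exact permutation p = 1.6e-04, the smallest that 12870 arrangements allow). Probes without a bovine gene of their name or number had sample medians of 160 ± 44.0 normalized counts in run 1 and 57.5 ± 15.9 in run 2, while probes with one had 200.1 ± 23.8 and 350 ± 37.4 (each exact permutation p = 1.6e-04). The median over all probes was 0.74 log2 units higher in run 2. After rescaling to one geometric mean it was 0.38 higher, and 121 probes were called, 77 higher and 44 lower; after quantile normalization it was 0.18 higher, and 94 were called, 57 higher and 37 lower. miR-424-5p was then not called (adjusted p = 0.0877). Every day has the same number of samples in each run, and the limma tests of day held the run term unless stated.

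Of the lists fixed in advance, 5 had too few probes to test. The miR-34 family had 1 measured member, miR-34a-5p, with a log2 difference of 0.57 on day 23 against day 14 (adjusted p = 0.280). The erythroid list had 1, miR-451a, with -1.04 (adjusted p = 0.176), and the epithelial miR-200 and miR-183 list had 2, miR-141-3p with 0.29 (adjusted p = 0.540) and miR-183-5p with -0.54 (adjusted p = 0.429). The skeletal muscle, liver and neural list and the hypoxia list had 0 measured members.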

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

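The sample total and the miRNAs named for a comparison or for abundance, 47 items in all, were examined for a sample far from the other 3 of its day. Of 188 groups of 4, 13 held such a value, where chance gives about 9.4; 12 of the 13 were run 2 samples, and 4 were in day 17 replicate 4. Each group mixes both runs, and neither this test nor the chance count takes the run into account. In that sample miR-143-3p was 2846 (others 637 to 938), miR-376c-3p 313 (87.6 to 106), miR-424-5p 3886 (436 to 1023) and miR-21-5p 6836 (2111 to 2666). In day 17 replicate 3, miR-181a-5p was 13130 (5984 to 6515) and miR-197-3p 420 (97.7 to 151), and in day 17 replicate 2, the run 1 sample, miR-141-3p was 49.2 (37.1 to 39.0). In day 20 replicate 4, miR-424-5p was 2154 (677 to 875) and miR-126-3p 29618 (8683 to 10472). In day 14 replicate 4, miR-92a-3p was 386 (177 to 213) and miR-652-3p 725 (103 to 185). In day 23 replicate 3 the probe shared by miR-4454 and miR-7975 was 24031 (7553 to 10367), and in day 23 replicate 4 miR-328-3p was 178 (43.7 to 66.3).

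For the difference between runs, the tests of one scaling factor and of higher signal from probes without a bovine gene were chosen after the result was seen. The bovine probes were mostly higher in run 2 and the probes with no bovine gene mostly lower. One scaling factor between runs is excluded as the only cause, because 121 of 204 probes (59.3%) still differed after rescaling to one geometric mean, against 170 before. The low level of the probes without a bovine gene is excluded too: after that rescaling their median was -1.22, at percentile 0 of level-matched random lists, whose range was 0.20 to 0.44. Higher signal in run 1 from probes without a bovine gene is left open. The difference of medians between the 2 kinds of probe (-1.65) restates the pattern that prompted it, and genes were matched by name, not by sequence. Chance can be excluded, as 170 calls compare with a highest of 95 among the other splits, the real one being 1 of 100 as large.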

How the results depend on the processing

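No called list reversed direction under any alternative run, and no miRNA named for a call or for its small p did. Directions were not followed for lists that were not called, list members outside the rule, or the other probes called between runs. Other pseudocounts, no filter and a variance without trend moved no call. In the day tests the replicate block changed no call. It gave 1 miRNA for day 23 against day 14, 1 slope, 4 list calls and 0 elsewhere among these tests. The block takes the place of the run term, so the difference between runs was not tested under it. For the calls below that changed, the cause was not tested, except that fewer probes or samples were tested in the filtered and reduced fits. The list call of smooth muscle, pericyte and fibroblast miRNAs on day 17 was lost with a filter at 100 (0.32, adjusted p = 0.0764 by limma), without the run term (0.32, 0.0532) and with quantile normalization (0.32, 0.117). Without the run term day 23 against day 14 gave 0 calls and the slope 0. Geometric mean scaling gave 3 slopes; quantile normalization gave 2 calls for day 23 against day 14, 9 slopes and 94 probes between runs.

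Run 1 alone gave 40 calls among the 4 days, 5 for day 17 against day 14, 31 for day 20 against day 14, 40 for day 23 against day 14, 1 for day 20 against day 17, 4 for day 23 against day 20, 9 slopes, miR-432-5p not among them, and 12 list calls. Of the 40 for day 23 against day 14, 20 had the same direction in run 2. Run 2 alone gave 0 for day 23 against day 14 and 0 slopes, and lost the lists DLK1-DIO3 for day 23 against day 20 (-0.23, adjusted p = 0.151 by limma) and smooth muscle on day 17 (0.14, 0.844). With an estimated correlation 0 list calls were left: DLK1-DIO3 -0.56 (0.225), -0.44 (0.0920) and -0.41 (0.266) against days 14, 17 and 20, and smooth muscle 0.32 (0.676). The 8 samples of days 14 and 23 alone gave 0 calls. Chosen after seeing the data, bovine-matched probes only gave 2 slopes and smooth muscle 0.32 (0.0529), and leaving out the lowest and highest totals gave 0 calls for day 23 against day 14, 0 slopes and smooth muscle 0.15 (0.360).

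Leaving out each sample in turn, the 4 days and the other 5 pairs of days stayed at 0 to 0. Day 23 against day 14 gave 0 to 10 calls: 0 without day 14 replicates 1 or 3 or day 23 replicates 1 or 4, 3 without day 14 replicate 4 and 10 without day 23 replicate 3. Slopes were 0 to 11: 0 without day 14 replicates 1 or 3, day 17 replicates 1 or 2, day 20 replicates 2 or 4, or day 23 replicates 1, 2 or 4, then 2 without day 20 replicate 1, 3 without day 17 replicate 3, 9 without day 14 replicate 4 and 11 without day 23 replicate 3. Run calls were 159 to 170. List calls were 3 to 9: 9 without day 14 replicate 3, 8 without day 14 replicate 4 or day 20 replicate 4, and 7 without day 20 replicate 1 or day 23 replicate 3. The DLK1-DIO3 median stayed called, at -0.64 to -0.43 against day 14, -0.51 to -0.36 against day 17 and -0.54 to -0.22 against day 20. Smooth muscle ran from 0.15 to 0.60 and lost its call without day 14 replicate 1 (adjusted p = 0.396 by limma), 2 (0.132) or 4 (0.143), or day 17 replicate 2 (0.195) or 4 (0.151). Among named miRNAs that were not called, one sample moved these by over 1.5 times. On day 20 against day 17, the probe shared by miR-4454 and miR-7975 (0.88) was 0.38 without day 17 replicate 3 and 1.34 without day 17 replicate 1, miR-4516 (-1.39) was -0.90 without day 17 replicate 3, and miR-542-3p (-0.63) was -0.35 without day 17 replicate 4 and -0.41 without day 20 replicate 3. On day 23 against day 20, miR-328-3p (0.79) was 0.52 without day 20 replicate 1 and 0.50 without day 23 replicate 4, and miR-574-5p (0.80) was 0.46 without day 20 replicate 4. Without day 14 replicate 1, miR-125b-5p on day 17 (0.62) was 0.39 and miR-656-3p on day 20 (-0.79) was -0.51.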

Other observations

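The miR-17 to miR-92 clusters, which are transcribed as joint precursors and linked to cell proliferation, held members on both sides on day 23 against day 14; these members were chosen after their values were seen. miR-19a-3p averaged 72.3 ± 12.0 normalized counts on day 14 (SD, n = 4) and 38.1 ± 24.8 on day 23 (log2 -1.08, SE 0.38, adjusted p = 0.124 by limma), while miR-92a-3p averaged 246 ± 94.8 and 493 ± 375 (log2 0.79, SE 0.37, adjusted p = 0.218). Run means of miR-19a-3p went from 62.7 to 29.1 and from 81.9 to 47.2, and those of miR-92a-3p from 192 to 272 and from 299 to 714. The blood cell miRNA miR-451a, also chosen after its values were seen, averaged 774 ± 762 on day 14 and 284 ± 106 on day 23, with run means going from 271 to 210 and from 1276 to 357. The share of let-7a-5p and let-7b-5p in the total was 35.9% ± 3.05 on day 14 and 40.9% ± 3.83 on day 23, a difference of 5.02 points (exact permutation p = 0.143).

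For the lower DLK1-DIO3 list on day 23, the tests of run, scaling and stromal RNA were chosen after the result was seen. The list was lower in both runs. With each sample rescaled to one geometric mean the median was -0.35 in run 1 (16 of 18 below 0, SE over members 0.10) and -0.69 in run 2 (14 of 18, SE 0.15). Without rescaling it was -0.26 and -0.76, so its size differed between runs. An SE over members does not measure the spread between animals, so it cannot exclude a difference held by one run only. Under the 2 other scalings the median was -0.42 at its nearest to 0, against -0.56. The mean geometric means of days 14 and 23 were already alike (258.9 and 259.8), so rescaling to one geometric mean could hardly move it. The normalization of the deposited values is not given, so scaling is not excluded. The level of the members is excluded, because the median lay at percentile 0 of 10000 level-matched lists (1st percentile -0.18). Less smooth muscle, pericyte and fibroblast RNA is left open. That list lay 0.52 log2 units above the cluster against day 14 (SE over members 0.20), over 2 such SE. The difference was 0.14 against day 17 (SE 0.19) and 0.058 against day 20 (SE 0.14). Chance is not excluded, since the list was followed up because it was called among 84 pairs of list and comparison, although the real split was the largest of 35 against day 14 (-log10 p 5.43, highest other 5.25, 1 of 35 as large) and day 17 (7.16, highest other 6.60, 1 of 35) and was 1 of 2 as large against day 20 (5.13, highest other 5.75, 2 of 35).

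For the higher smooth muscle, pericyte and fibroblast list on day 17, no test was chosen after the result was seen. By the rule written beforehand, a median above the upper limit of level-matched lists counts against a general rise of abundant miRNAs. The median lay at percentile 98.9 of those lists, only a little above that limit (0.32 against 0.29). Because the margin was small, the general rise is left open despite the rule. Chance cannot be excluded (-log10 p 2.60, highest other split 8.12, 7 of 35 as large).

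Regrouping the samples tested the counts of calls in the same way. Chance cannot be excluded for day 23 against day 14 (1 call, highest other split 3, 3 of 35 as large), for the slope (1, highest other 19, 6 of 100) or for the lists (4, highest other 16, 74 of 100). The other day tests had 0 calls, so all splits were as large: 35 of 35 for day 17 against day 14 (highest other 42), day 20 against day 14 (2), day 20 against day 17 (12), day 23 against day 17 (12) and day 23 against day 20 (0), and 100 of 100 for the 4 days (8). The 42 calls came from setting day 14 replicates 1 and 2 with day 17 replicates 2 and 3 against the other 4 samples. That split was the largest of 35, and whether it reflects a structure of the samples was not tested. Of the 4 samples set together, 3 are from run 1 and 1 is from run 2.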
